A study of Mus musculus with 10 samples.

How the data were processed

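Single-cell RNA of dissociated stomach mucosa was measured in 10 mice, 1 droplet library per mouse, from 4 groups named in the labels: TY (control, n = 2), TP (Pten knockout, n = 3), TCD (Kmt2c and Kmt2d double knockout, n = 3) and TPCD (knockout of all 3 genes, n = 2). Per the labels' protocols, stomachs were taken 3 weeks after tamoxifen, stripped mucosa was digested, cells negative for DAPI were sorted as viable, and 3′ libraries were made with a Chromium kit. The deposited values are UMI counts per gene and barcode, made with Cell Ranger 7.0.0 on GRCm38 (mm10), per the labels' processing notes. The matrices are unfiltered, with 31056 genes, and hold empty droplets as well as cells. Groups were taken from the labels. Gene IDs are those of the files, and all 327 named IDs were found in GENCODE vM21, which gave the coordinates.

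Barcodes with at least 1000 UMIs, at least 500 genes and at most 30% mitochondrial UMIs were called cells, 67978 in all. Scrublet, as run by scanpy, marked between 0 and 3.9% of cells at its automatic threshold. A fixed rate was therefore used: in each library the cells with the highest scores were removed at 0.8% per 1000 called cells, 4375 in all, which left 63603. Counts were scaled to 10000 per cell and logged. On 1995 variable genes, with mitochondrial, ribosomal, haemoglobin, sex-linked and transgene sequences left out, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python 3.11.15), which gave 52 clusters. Libraries were not integrated.

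The files hold no cell types, so clusters were named from fixed marker lists. A class needed at least 3 markers at 50 CPM or more and at least 2-fold above all other cells, a lead of 0.5 in mean log2 fold over the next class, and no other class with more markers among the 10 leading genes. Clusters with no name, Epcam of at least 400 CPM, Cldn18 of at least 500 CPM and no set of 3 markers of a class outside the glands were kept as unnamed epithelial cells, and the rest stayed unassigned (between 0.0325 and 22.1% of a library). These thresholds were set after several versions had been compared on the clusters. Pit-like cluster 2, of whose 4293 cells 3263 came from the library labelled TP replicate 3, had haemoglobin genes beside its pit markers among its 10 leading genes. Glandular epithelial cells are the pit-like, neck-like, chief-like, parietal-like, cycling and unnamed epithelial cells.

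Raw counts were summed per library over all glandular epithelial cells, and over pit-like, neck-like and chief-like cells in libraries with at least 30 such cells. The sums were tested across libraries with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05), with all libraries in 1 fit and 4 group means. The comparisons were TP, TCD and TPCD against TY, TPCD against TP and against TCD, the average effect of Pten loss, the average effect of Kmt2c and Kmt2d loss, and the interaction, which is the Pten effect in cells without Kmt2c and Kmt2d minus that in cells with them. Values are CPM with the SD over libraries, and log2 folds with their standard errors. Of 37 fixed gene lists, 35 had at least 5 members among the 17063 tested genes and were tested with camera (limma 3.58.1, preset correlation 0.01), with fry, and with camera at an estimated correlation. Camera asks whether a list moves more than other genes, while fry asks whether its members move, on balance, one way. Shares of cells were compared with an exact two-sided permutation test over all 25200 assignments of the 10 libraries to the 4 groups. Classes held by different clusters in different groups are given as values only.

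Named genes were the 8 with the largest rise and the 8 with the largest fall per comparison, among genes past the threshold with a mean of at least 20 CPM in the higher group and no overlap between libraries. Gene models without a name and mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes were left out. The 3 targeted genes and up to 4 members of each list described were added. The samples, tests, gene lists, markers and this rule were fixed before the data were examined. The 3 transgene sequences were also left out of the naming, although the written rule did not say so, and the EYFP reporter is described by itself. A fold against a group with 0 counts is given as a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% counting interval. Such intervals cover counting error only.

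The alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, each library left out in turn, the replicate number as a block, a fit of only the groups compared, at least 2000 UMIs per cell, at most 15% mitochondrial UMIs, doublets kept, Leiden resolution 2 (77 clusters), cells thinned to 1000 UMIs, and subtraction of free RNA. For the last, the profile of barcodes with 10 to 100 UMIs was subtracted from each sum, at a share estimated from gastric secretory genes in immune-like and stromal cells. A further alternative left out the libraries labelled TP replicate 3 and TCD replicate 1 together and was chosen after seeing the data. Tests in myeloid-like, fibroblast-like and T and NK-like cells were also chosen after seeing the data.

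The tests were tested on simulated counts with the real genes' means, spread and library sizes. edgeR recovered 42.7% of 4-fold changes for TP against TY, 40% for TCD against TY, 22.7% for TPCD against TY, 37.5% for TPCD against TP, 40.8% for TPCD against TCD, 81.4% for the average Pten effect and 76% for the average Kmt2c and Kmt2d effect, but 0% for the interaction. Recovery of 2-fold changes was 4.21% for TP against TY and 22.4% for the average Pten effect. Of edgeR's calls in these simulations at most 11.4% were false (TPCD against TP), against 20 to 45% of DESeq2's, which is why DESeq2's larger counts are given beside edgeR's and not in their place. Few genes were changed in each simulation (for TP against TY 95 by 2-fold and 96 by 4-fold among 16394). Rates of recovery and of false calls may therefore differ in the data, where more genes passed in most comparisons. Camera called the 3 moved lists in each simulation and at most 2 others. Genes were drawn independently of each other there, so the simulations do not test camera's preset correlation. The share test gave a p under 0.05 in 5% of simulations with no difference.

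Total UMIs ran from 36189999 to 149902509 per library and the UMIs in epithelial sums from 23893026 to 111806937. Median UMIs per cell ran from 3405 to 16738, so that classes and shares were read from cells of unequal depth.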

Results

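RNA was measured in single cells of mouse stomach mucosa from 4 groups: control mice (TY, n = 2), mice with Pten deleted (TP, n = 3), mice with both Kmt2c and Kmt2d deleted (TCD, n = 3) and mice with all 3 genes deleted (TPCD, n = 2). Pten encodes a lipid phosphatase that restrains PI3K signalling, and Kmt2c and Kmt2d encode histone methyltransferases that act at enhancers. Each library came from 1 mouse. Total UMIs were 68489510 and 97695598 in TY replicates 1 and 2, and 115803290, 134638850 and 110236009 in TP replicates 1, 2 and 3. They were 36189999, 80606873 and 58762987 in TCD replicates 1, 2 and 3, and 149902509 and 143428197 in TPCD replicates 1 and 2. After filtering, 63603 cells were kept, between 1529 (the library labelled TCD replicate 1) and 10585 (the library labelled TP replicate 3) per library. Glandular epithelial cells numbered 986 to 6442 per library. The epithelial sums pool all glandular classes, so their changes can come from class make-up as well as from change within a class. Transcripts of the EYFP reporter were present in TY and TPCD and nearly absent from TP and TCD, so each comparison of TP or TCD with TY or TPCD also set mice with the reporter transcript against mice without it.

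The targeted genes were read first in the epithelial sums, on GRCm38 (mm10). Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, plus strand) stood at 120 and 112 CPM in TY, and at 66.4, 61.6 and 63.6 CPM in TP replicates 1 to 3. It stood at 58.5, 85.1 and 76.8 CPM in TCD replicates 1 to 3 and at 59.6 and 60.8 CPM in TPCD. Pten fell in TPCD against TY by 0.95 on the log2 scale (SE 0.20, edgeR adjusted p = 0.0073), while its log2 fold in TP against TY, -0.86, did not pass (adjusted p = 0.077). Kmt2c (ENSMUSG00000038056, chromosome 5, 25271798 to 25498783, minus strand) stood at 117 and 130 CPM in TY, at 150, 163 and 47.8 in TP, at 170, 96.1 and 93.9 in TCD and at 92.8 and 86.1 in TPCD. Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98871204, minus strand) stood at 19.6 and 20.4 CPM in TY, at 19.9, 20 and 10.7 in TP, at 23.2, 12.6 and 11.3 in TCD and at 10.4 and 11 in TPCD. Neither Kmt2c nor Kmt2d passed in any comparison of all 10 libraries. Within TP, the library labelled replicate 3 was low in both, and within TCD, the library labelled replicate 1 was high in both, beside the other libraries of their groups. Without both libraries, which were doubted in part for these levels, Kmt2c passed at 0.32 in TP against TY, and Kmt2c and Kmt2d passed at -0.40 and -0.77 in TCD against TY. The 3′ tags may lie outside the deleted parts, so these levels do not show which mice carried the deletions. Counts of genes are therefore also given without both of these libraries, an alternative chosen after seeing the data.

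**Figure D1:**
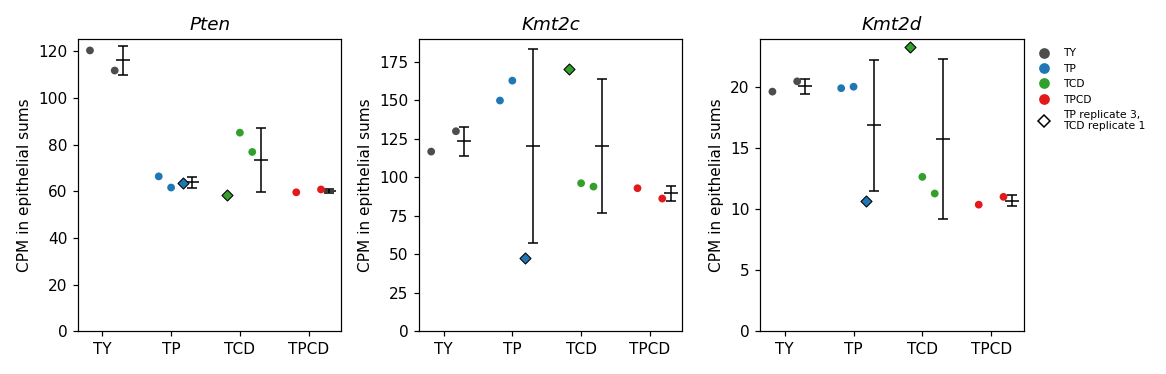
Epithelial CPM of Pten, Kmt2c and Kmt2d (vertical axes) per library in the 4 groups (horizontal axes), with points for libraries, bars for the mean and lines for the SD; diamonds mark the libraries labelled TP replicate 3 and TCD replicate 1. Kmt2c stood at 47.8 CPM in the former and at 170 CPM in the latter.

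TPCD against TY asks what loss of all 3 genes did to the gastric epithelium. Most measured genes of parietal and chief cells fell, and most measured squamous and NF-kB genes rose. Among 17063 genes tested, 2703 rose and 2712 fell (5415 in all, edgeR; 10876 without both libraries named above). Pgc, the pepsinogen of chief cells, fell from 50800 CPM (SD 3130, n = 2) to 27.4 CPM (SD 1.73, n = 2), a log2 fold of -10.85 (SE 1.26, adjusted p = 0.00058). The NF-kB inhibitor Tnfaip3 rose from 8.33 CPM (SD 0.0606) to 161 CPM (SD 0.722), a log2 fold of 4.27 (SE 0.24, adjusted p = 4.2e-05).

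Of 16 genes of acid-secreting parietal cells measured, 12 fell in TPCD (14 adjusted over the list alone; camera adjusted p = 2.15e-09, and adjusted p = 0.153 with an estimated correlation). The proton pump genes Atp4b and Atp4a fell from 4780 to 0.468 CPM and from 4850 to 1.1 CPM. The histamine receptor gene Hrh2 had a log2 fold of -7.76 (SE 0.42) and the channel gene Kcne2 of -8.43. Of 13 chief cell genes, 7 fell (7 adjusted over the list alone; camera adjusted p = 0.000197, and adjusted p = 0.182 with an estimated correlation). They include the colipase gene Clps (86200 to 18.3 CPM) and the cholecystokinin receptor gene Cckar (-9.09). The phospholipase gene Pla2g1b fell from 51100 to 4.94 CPM. Of 19 pit cell genes, 2 rose and 8 fell (camera adjusted p = 0.0362, and adjusted p = 0.535 with an estimated correlation), with the surface mucin gene Muc5ac at a log2 fold of -4.76 (SE 0.42) and Psca at -8.23. The gasdermin gene Gsdma2 (-13.04, SE 1.12), the hepcidin gene Hamp2 (-13.08), the retinol dehydrogenase gene Rdh7 (ratio 15400, counting interval 2760 to 608000) and the cystatin gene Cst8 (at least 1980-fold lower, adjusted p = 0.0054) also fell. Of 22 oxidative phosphorylation genes, 16 fell (21 adjusted over the list alone; camera adjusted p = 2.86e-07, and adjusted p = 0.528 with an estimated correlation), among them Sdha (-1.52), Ndufs7 (-1.67) and Sdhb (-1.74).

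Of 17 squamous genes measured in the glandular sums, 14 rose in TPCD (14 adjusted over the list alone; camera adjusted p = 2.86e-07, and adjusted p = 0.173 with an estimated correlation). The basal keratin gene Krt14 rose from 0.0887 to 83.4 CPM (SD 48.7), a log2 fold of 9.62 (SE 0.85, adjusted p = 7e-05). Krt16 rose by 10.02 (SE 2.22), Krt13 by 8.15 (SE 1.18) and Krt6a at least 180-fold. Krt14 also stood at 54.3 CPM in the myeloid-like sums of TPCD (0.382 in TY), and squamous-like cells were 3.52% of TPCD cells, which leaves open how much of this RNA came from other cells. With free RNA subtracted Krt14, TPCD vs TY, still passed (adjusted p = 0.0017). Tacstd2, a surface protein gene of stratified epithelia, rose at least 702-fold and the annexin gene Anxa8 by 8.98. Of 15 claudin and junction genes, 9 rose (10 adjusted over the list alone; camera adjusted p = 6e-04, and adjusted p = 0.153 with an estimated correlation), with Cldn7 at 312 against 7.63 CPM (5.35, SE 0.52) and Cldn23 at 4.47.

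Of 23 NF-kB genes in the same cells, 18 rose (19 adjusted over the list alone; camera adjusted p = 2.15e-09, and adjusted p = 0.153 with an estimated correlation), including Relb (2.19), Birc3 (2.62) and Nfkbia (2.29). The neutrophil chemokine gene Cxcl5 reached 197 CPM (SD 146) against 1 count in TY (ratio 16200, counting interval 2910 to 639000). The growth factor gene Ereg reached 95.1 CPM (ratio 3930, interval 1090 to 32500), the lipocalin gene Lcn2 45 CPM (ratio 1850, interval 513 to 15300), and the lactoferrin gene Ltf rose at least 925-fold (adjusted p = 0.023). Of 24 interferon response genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 2.43e-05, and adjusted p = 0.535 with an estimated correlation), among them Rtp4 (4.14), Bst2 (2.91) and Mx1 (5.42). Of 18 immune cell markers, 5 rose in the epithelial sums, with Cd68 at 2.74, and the list did not pass (camera adjusted p = 0.0945). Of 5 red cell markers, 4 fell (Hbb-bs -7.84; camera adjusted p = 0.0273, and adjusted p = 0.535 with an estimated correlation).

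Of 20 cholesterol synthesis genes, 15 rose (18 adjusted over the list alone; camera adjusted p = 2.86e-07, and adjusted p = 0.354 with an estimated correlation), among them Hsd17b7 (2.40) and Msmo1 (2.02). Of 19 ATF4 targets and amino acid genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000182, and adjusted p = 0.371 with an estimated correlation), with the cystine transporter gene Slc7a11 at 61.5 against 4.52 CPM (3.77, SE 0.27) and the serine synthesis gene Psat1 at 2.37. Of 19 p53 targets, 12 rose (12 adjusted over the list alone; camera adjusted p = 3.58e-05, and adjusted p = 0.354 with an estimated correlation), including Trp53inp1 (1.62), Pmaip1 (2.23) and Eda2r (7.02). Of 16 TGF-beta and mesenchymal transition genes, 10 rose (12 adjusted over the list alone; camera adjusted p = 3.95e-05, and adjusted p = 0.153 with an estimated correlation), including the laminin gene Lamc2 (3.27), Zeb1 (3.98) and Serpine1 (7.09). Of 15 hypoxia genes, 8 rose (8 adjusted over the list alone; camera adjusted p = 0.000685, and adjusted p = 0.371 with an estimated correlation), with the glucose transporter gene Slc2a1 at 1.67. The count of 5415 became 2250 and 2595 without TY replicate 1 or 2, and 2955 and 2616 without TPCD replicate 1 or 2. With free RNA subtracted it was 1881 and at most 15% mitochondrial UMIs 3355.

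**Figure D2:**
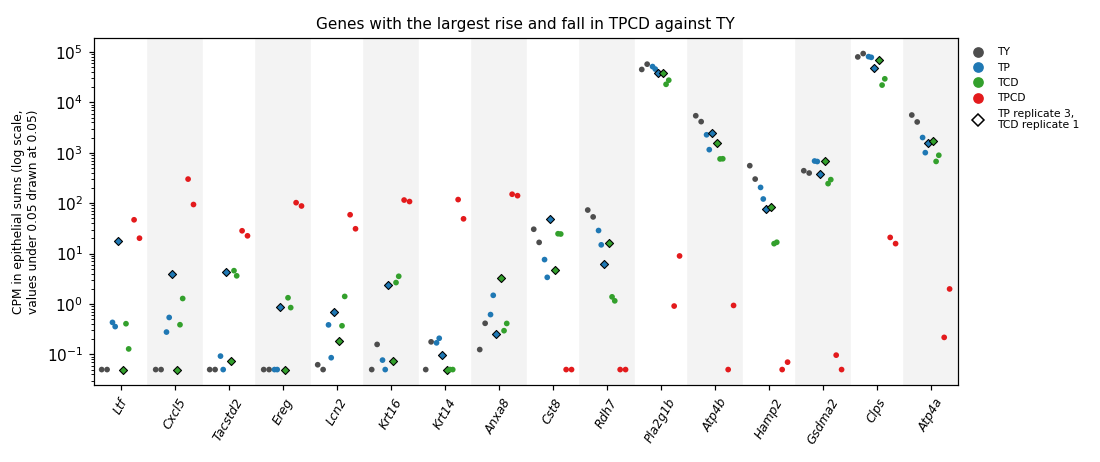
Epithelial CPM (log axis, values under 0.05 drawn at 0.05) of the 16 genes with the largest rises and falls in TPCD against TY, with a point per library of all 4 groups. Atp4b averaged 4780 CPM in TY and 0.468 CPM in TPCD, and Krt14 0.0887 and 83.4 CPM.

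TP against TY asks what loss of Pten alone did. Some interferon response and MHC class I genes rose, and Kif1a and Gcnt2 led the falls. In all 30 genes rose and 37 fell (67, edgeR; 3495 without both libraries named above). Bst2, which tethers budding viruses, rose from 11.5 CPM (SD 0.815, n = 2) to 108 CPM (SD 12.2, n = 3), a log2 fold of 3.23 (SE 0.28, adjusted p = 0.0042).

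Of 24 interferon response genes, 6 rose (19 adjusted over the list alone; camera adjusted p = 1.17e-21, and adjusted p = 0.345 with an estimated correlation). The antiviral genes Oas2, Mx1, Rtp4, Irf7 and Gbp2 had log2 folds of 5.89 (SE 0.68), 4.71 (SE 0.69), 4.08 (SE 0.34), 3.65 (SE 0.49) and 3.67 (SE 0.33). Of 14 MHC class I genes, 4 rose (10 adjusted over the list alone; camera adjusted p = 7.42e-14, and adjusted p = 0.298 with an estimated correlation). They were the immunoproteasome genes Psmb8 (2.31) and Psmb9 (2.00), H2-Q7 (5.18) and the peptide transporter gene Tap1 (2.46). The further interferon-linked genes Oasl1 (1.88) and Nmi (1.30) also rose. Of 18 immune cell markers, 1 rose (16 adjusted over the list alone; camera adjusted p = 1.49e-08, and adjusted p = 0.455 with an estimated correlation). That gene, Jchain of plasma cells, stood at 16.9 against 0.0197 CPM (ratio 600, counting interval 166 to 4960). All 5 red cell markers rose only when adjusted over the list alone (camera adjusted p = 0.000144, and adjusted p = 0.455 with an estimated correlation).

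The falls were led by the kinesin gene Kif1a (-3.33, SE 0.42), the glycosyltransferase gene Gcnt2 (-2.64, SE 0.23; 62.1 to 9.97 CPM), the dystrobrevin gene Dtna (-2.00) and the ankyrin gene Ank3 (-1.75, 750 to 223 CPM). Lonrf1 (-1.62), Rab30 (-1.60), the lipid kinase gene Pi4k2a (-1.56, SE 0.16) and Arhgef38 (-1.49) followed. Of 23 FoxO targets, 0 passed over all genes by edgeR (5 lower adjusted over the list alone; camera adjusted p = 3.95e-05, and adjusted p = 0.298 with an estimated correlation). Of 16 parietal genes, 0 passed (5 lower adjusted over the list alone; camera adjusted p = 1.77e-06, and adjusted p = 0.345 with an estimated correlation). Over all genes 2214 had an unadjusted p under 0.05, and DESeq2 called 729. With free RNA subtracted edgeR called 8, and at most 15% mitochondrial UMIs 13. Leaving out any single library moved the count of 67 by more than 1.5 times, to 2 without TY replicate 1 or 2, to 29, 18 and 195 without TP replicates 1, 2 and 3, to 195, 11 and 7 without TCD replicates 1, 2 and 3, and to 8 without TPCD replicate 1 or 2.

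TCD against TY asks what loss of Kmt2c and Kmt2d did with Pten present. Most measured interferon response genes rose, and most of the genes that passed fell. In all 156 genes rose and 379 fell (535, edgeR; 7566 without both libraries named above). Rnase1, a secreted ribonuclease gene, fell from 183 CPM (SD 13.6, n = 2) to 18.3 CPM (SD 13.2, n = 3), a log2 fold of -3.32 (SE 0.56, adjusted p = 0.028).

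Of 24 interferon response genes, 13 rose (18 adjusted over the list alone; camera adjusted p = 5.67e-13, and adjusted p = 0.694 with an estimated correlation), among them Oas2 (6.18, SE 0.69), Isg15 (4.30, SE 0.88), Oasl2 (4.12), Rtp4 (4.05, SE 0.34), Gbp2 (4.01) and Bst2 (3.09). Of 14 MHC class I genes, 6 rose (10 adjusted over the list alone; camera adjusted p = 3.13e-09, and adjusted p = 0.694 with an estimated correlation), with H2-Q7 at 5.78 and Psmb8 at 2.87. Mx1 (4.47), Xaf1 (3.63) and Irf7 (3.62) rose too. Of 22 oxidative phosphorylation genes, 1 fell (12 lower adjusted over the list alone; camera adjusted p = 9.06e-09, and adjusted p = 0.811 with an estimated correlation), the succinate dehydrogenase gene Sdha (-1.09, SE 0.18; 241 to 113 CPM). Of 16 parietal genes, 4 fell (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.24e-06, and adjusted p = 0.694 with an estimated correlation): Clic6 (-1.85), the mitochondrial regulator Ppargc1a (-1.75), Slc4a2 (-1.33) and Hrh2 (-1.32).

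Beside Rnase1, the falls named by size were in Kif1a (-3.94, SE 0.44), Hamp2 (-3.46, SE 0.76), the fatty acid binding gene Fabp12 (-3.19, SE 0.71), Hsbp1l1 (-2.86), the growth factor binding gene Igfbp2 (-2.81), the fatty acid receptor gene Cd36 (-2.76) and the Cajal body gene Coil (-2.72). Slc7a11 rose by 1.16 (SE 0.23, adjusted p = 0.037) and Lamc2 by 1.71. The FoxO target Cat, which encodes catalase, fell from 132 to 36.3 CPM, and the p53 target Cdkn1a fell from 122 to 52.4 CPM. The count of 535 became 5 and 9 without TY replicate 1 or 2, 331 and 2200 without TP replicate 1 or 3, 1871, 7 and 6 without TCD replicates 1, 2 and 3, and 55 without TPCD replicate 1 or 2. With free RNA subtracted it was 18 and at most 15% mitochondrial UMIs 12.

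TPCD against TP asks what loss of Kmt2c and Kmt2d added where Pten was lost. Most measured squamous genes rose and most measured chief and parietal genes fell. In all 2303 genes rose and 2454 fell (4757, edgeR; 10525 without both libraries named above). The laminin gene Lama3 rose from 0.389 CPM (SD 0.0438, n = 3) to 53.4 CPM (SD 8.79, n = 2), a log2 fold of 7.09 (SE 0.32, adjusted p = 1.1e-05).

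Of 17 squamous genes, 13 rose (14 adjusted over the list alone; camera adjusted p = 3.16e-08, and adjusted p = 0.13 with an estimated correlation), led by Krt14 (8.98, SE 0.66) and with Krt16 at 7.12. Of 23 NF-kB genes, 13 rose (14 adjusted over the list alone; camera adjusted p = 3.16e-08, and adjusted p = 0.13 with an estimated correlation), with Tnfaip3 at 3.86 (SE 0.20) and Relb at 2.24. The activin antagonist gene Fst (7.64), the matrix gene Fbln2 (7.27, SE 0.43), the cytokine gene Il1a (7.24), Ereg (8.49) and Anxa8 (7.50) rose as well. Of 19 p53 targets, 12 rose (12 adjusted over the list alone; camera adjusted p = 1.29e-06, and adjusted p = 0.247 with an estimated correlation), with Trp53inp1 at 2.20. Cldn7 rose by 5.71.

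Of 16 parietal genes, 12 fell (13 adjusted over the list alone; camera adjusted p = 3.16e-08, and adjusted p = 0.13 with an estimated correlation), with Atp4b at -12.04 and Atp4a at -10.43. Of 13 chief genes, 10 fell (10 adjusted over the list alone; camera adjusted p = 3.38e-05, and adjusted p = 0.13 with an estimated correlation), among them Pgc (-10.47, SE 1.24), Clps (-11.88) and the intrinsic factor gene Gif (-7.61). Gsdma2 (-13.51), Pla2g1b (-13.16), Hamp2 (-11.41) and the chitinase gene Chia1 (-10.01) had the other large falls. Of 10 endocrine genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.00551, and adjusted p = 0.332 with an estimated correlation), with the somatostatin gene Sst at -7.55. The 5 red cell markers all fell (camera adjusted p = 0.00111, and adjusted p = 0.404 with an estimated correlation) and 6 of 18 immune markers fell. The count of 4757 became 3134 without TP replicate 1, 2122 and 1850 without TPCD replicate 1 or 2, and 1958 with free RNA subtracted.

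TPCD against TCD asks what loss of Pten added where Kmt2c and Kmt2d were lost. Most measured NF-kB, cholesterol synthesis and squamous genes rose and most measured parietal genes fell. In all 1706 genes rose and 1719 fell (3425, edgeR; 8649 without both libraries named above). Fbln2 rose from 0.0371 CPM (SD 0.0371, n = 3) to 24 CPM (SD 2.25, n = 2), a log2 fold of 9.41 (SE 0.53, adjusted p = 9.4e-06).

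Of 23 NF-kB genes, 18 rose (20 adjusted over the list alone; camera adjusted p = 1.25e-12, and adjusted p = 0.077 with an estimated correlation), with Tnfaip3 at 4.40 and the chemokine gene Cxcl2 at 285 against 0.747 CPM (8.51, SE 0.87). Cxcl5 (8.41), Il1a (8.20), Fst (7.35), Ltf (7.26) and the germ cell gene Asz1 (7.84) also rose. Of 17 squamous genes, 12 rose (13 adjusted over the list alone; camera adjusted p = 1.44e-08, and adjusted p = 0.113 with an estimated correlation), led by Krt14 (ratio 4970, counting interval 1380 to 41000). Of 20 cholesterol synthesis genes, 15 rose (19 adjusted over the list alone; camera adjusted p = 3.17e-09, and adjusted p = 0.196 with an estimated correlation), with Msmo1 at 1.76. Of 16 glycolysis genes, 8 rose (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.82e-05, and adjusted p = 0.309 with an estimated correlation), with Ldha at 1.44. Of 22 S phase genes, 7 rose (11 adjusted over the list alone; camera adjusted p = 0.000219, and adjusted p = 0.529 with an estimated correlation), with Mcm6 at 1.04. Of 21 genes of spasmolytic polypeptide-expressing metaplasia, 7 rose (7 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.508 with an estimated correlation), with Dmbt1 at 4.14. Of 14 stromal markers, 5 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.339 with an estimated correlation), with Acta2 at 2.69.

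The falls were led by Gsdma2 (-13.01), Pla2g1b (-12.55), Atp4b (-11.09), Clps (-11.09), Atp4a (-9.96), Chia1 (-9.75), Pgc (-9.69) and Hamp2 (-9.62). Of 16 parietal genes, 12 fell (13 adjusted over the list alone; camera adjusted p = 3.9e-09, and adjusted p = 0.077 with an estimated correlation). The count of 3425 became 5869 without TP replicate 3, 2262 and 2223 without TCD replicate 2 or 3, 1306 and 1204 without TPCD replicate 1 or 2, and 1025 with free RNA subtracted.

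Averaged over both Kmt2c and Kmt2d states, 18 of 23 NF-kB genes were higher with Pten loss (21 adjusted over the list alone, camera adjusted p = 1.42e-13, and adjusted p = 0.12 with an estimated correlation). Of 16 parietal genes, 12 were lower (13 adjusted over the list alone, camera adjusted p = 3.62e-11, and adjusted p = 0.139 with an estimated correlation). The median interaction log2 fold of the NF-kB list was 1.62, so TPCD weighed most in its average. For TPCD the stomach region sampled stays open, as described below. In all 1004 genes rose and 1163 fell (2167, edgeR; 7397 without both libraries named above). The mast cell protease gene Mcpt2 (4.07, SE 0.24), Cxcl2 (5.59, SE 0.63), Tnfaip3 (2.40, SE 0.14), Wfdc2 (1.92), the protease gene Ctsc (1.10) and the cell cycle genes Cdk1 (0.95), Ube2c (0.75) and Pclaf (0.73) rose. Falls were in Arhgap28 (-1.98), Mtor (-0.91, SE 0.11), Pdgfd (-0.83), Wipi1 (-0.67), Fhit (-0.65), Nr1d2 (-0.64), Rb1cc1 (-0.63) and Rell1 (-0.63). Alternatives changed the sign of 2 of these: for Tnfaip3, average Pten effect, the fold was -3.58 (SE 0.63, adjusted p = 0.055) with free RNA subtracted, and for Rell1, average Pten effect, 0.09 at most 15% mitochondrial UMIs. Of 23 FoxO targets, 3 rose and 6 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.0232, and adjusted p = 0.297 with an estimated correlation), with Cat at -1.13, Txnip at -1.07, Irs2 at -0.80 and Fbxo32 at -0.77. Of 24 G2/M genes, 6 rose (12 adjusted over the list alone; camera adjusted p = 1.32e-05, and adjusted p = 0.395 with an estimated correlation), and 5 of 18 immune markers rose (8 adjusted over the list alone; camera adjusted p = 8.72e-05, and adjusted p = 0.395 with an estimated correlation). Across 17063 genes, which are not independent replicates, the Pten effects with and without Kmt2c and Kmt2d correlated at 0.186, and 60.7% of the 3462 genes called in either had the same sign. The count of 2167 became 637 and 810 without TY replicate 1 or 2, 3798 without TP replicate 3, 1404 without TCD replicate 3, and 857 and 758 without TPCD replicate 1 or 2. It was 314 with free RNA subtracted and 820 at most 15% mitochondrial UMIs.

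Averaged over both Pten states, most measured oxidative phosphorylation genes were lower with loss of Kmt2c and Kmt2d. Of 19 ATF4 targets and amino acid genes, 9 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.000203, and adjusted p = 0.439 with an estimated correlation). In all 2076 genes rose and 2298 fell (4374, edgeR; 10467 without both libraries named above). Ifitm3 (2.57, SE 0.20), the guanine deaminase gene Gda (2.38), Glis3 (2.35), Slc7a11 (2.32, SE 0.17), Lamc2 (2.15), Pmepa1 (1.79), Alpk1 (1.75) and Ddhd1 (1.64) rose. The nuclear receptor gene Nr0b2 (-5.62, SE 0.38), the fatty acid binding gene Fabp3 (-5.05, SE 0.31), Psca (-4.64), the growth factor gene Igf1 (-4.16, SE 0.19), Sst (-4.07), Sycn (-3.90), Rnase1 (-3.74) and the neuropeptide gene Npw (-3.26, SE 0.18) fell. Of 22 oxidative phosphorylation genes, 17 fell (21 adjusted over the list alone; camera adjusted p = 8.33e-08, and adjusted p = 0.439 with an estimated correlation), with Sdha at -0.85. Of 16 parietal genes, 12 fell as well (13 adjusted over the list alone; camera adjusted p = 3.6e-09, and adjusted p = 0.235 with an estimated correlation), and parietal-like cells were 39.3% of glandular cells in TY and 11.7% in TCD, and 14% in TP and 0.0618% in TPCD. Whether these falls, or those of oxidative phosphorylation genes, came from fewer parietal-like cells was not tested. Of 9 genes of the MLL3 and MLL4 complexes, 0 passed by edgeR or over the list (camera adjusted p = 0.982). The effects with and without Pten correlated at 0.369 across genes, and 72.8% of the 4956 genes called in either had the same sign. The count of 4374 became 2065 and 2373 without TY replicate 1 or 2, 6954 without TP replicate 3, 2915 without TCD replicate 2, and 2530 and 2165 without TPCD replicate 1 or 2. It was 1273 with free RNA subtracted and 2906 at most 15% mitochondrial UMIs.

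The interaction asks whether the response to Pten loss differed with Kmt2c and Kmt2d. Cldn7, the chemokine gene Cxcl1 and Phlda1 were highest after loss of all 3 genes, beyond the sum of the separate changes, and Gif and most measured interferon response genes were lower than that sum. In all 446 genes lay above it and 617 below (1063, edgeR; 5201 without both libraries named above). Mean CPM in TY, TP, TCD and TPCD was 7.63, 5.94, 4.01 and 312 for Cldn7 (6.63, SE 0.57, adjusted p = 0.00097), 6.82, 3.68, 1.88 and 73.2 for Cxcl1 (6.13) and 734, 1150, 1130 and 5.89 for Gif (-8.23, SE 1.23). Of 24 interferon response genes, 15 lay below the sum (21 below and 1 above adjusted over the list alone; camera adjusted p = 7.7e-12, and adjusted p = 0.229 with an estimated correlation), with Bst2 at -3.41 and Rtp4 at -3.98. Transcripts of the EYFP reporter stood at 1420 and 1190 CPM in TY and 1660 and 1740 CPM in TPCD, but at no more than 0.123 CPM in TP and TCD. The interaction sets TY and TPCD against TP and TCD, so anything that goes with the reporter enters it. The count of 1063 became 253 and 234 without TY replicate 1 or 2, 604 and 2330 without TP replicate 1 or 3, 586 and 573 without TCD replicate 2 or 3, and 286 and 364 without TPCD replicate 1 or 2. It was 192 with free RNA subtracted and 564 at most 15% mitochondrial UMIs.

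In neck-like cells 8 rose and 4 fell in TP against TY (12, edgeR), with the gastrin gene Gast at 2.86, Isg15 at 3.55, the lectin gene Reg3g at 4.45 and Wdfy1 at -2.00. The 12 became 5 with free RNA subtracted, 6 and 39 without TY replicate 1 or 2 and 2 without TP replicate 1. In chief-like cells 5 rose and 6 fell in TP against TY (11), with Isg15 at 3.91, Irf7 at 3.51, Bst2 at 2.38 and Slc35g1 at -2.33, and 7 rose and 3 fell in TCD against TY (10), with Bst2 at 2.63, Oasl2 at 3.54 and Slc35g1 at -3.12. The 11 of TP became 126 with free RNA subtracted (none of the 11 among them), 1 with cells thinned to 1000 UMIs, 74 without both libraries named above, 1 without TY replicate 1 or 2, 2 and 27 without TP replicate 2 or 3 and 7 without TCD replicate 2. The 10 of TCD became 0 with free RNA subtracted, 2 thinned, 800 without both libraries, 1 without TY replicate 1 or 2, 5 and 38 without TP replicate 2 or 3 and 20, 1 and 4 without TCD replicates 1, 2 and 3. Cluster 8 held most chief-like cells in TY, TP and TCD, but at Leiden resolution 2 most were in cluster 9 in TY and in cluster 23 in TCD. These genes of the smaller classes were picked after their values were seen. In pit-like cells edgeR called 0 genes in TP against TY and 0 in TCD against TY, with 298 and 776 at an unadjusted p under 0.05, with 70 and 132 called by DESeq2, and 580 and 2865 by edgeR without both libraries named above. Cluster 6 held the most pit-like cells in TY, cluster 2 in TP and cluster 7 in TCD, but libraries of the same group differed in this too. Cluster 6 held 508 cells of TY replicate 2 and 2520 of TP replicate 2, but 1 each of TY replicate 1 and TP replicate 1. Cluster 7 held 268 of TY replicate 1 and 1450 of TP replicate 1. The library labelled TP replicate 3 had 3263 cells in cluster 2. In TCD replicates 2 and 3 cluster 2 held 435 and 337 cells and cluster 7 held 386 and 323. In neck-like cells of TPCD against TY 2339 genes rose and 2503 fell (4842, 890 thinned), but cluster 41 held most of these cells in TPCD and cluster 9 in TY. Pit-like and chief-like cells of TPCD and neck-like cells of TCD were too few to test.

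Shares of cells are given per group as mean and SD. Squamous-like cells lay in 1 main cluster at resolution 1, but not at Leiden resolution 2. There cluster 60 (Cldn18 41.1 CPM) held 1 and 61 of TY, and cluster 40 (Cldn18 1895 CPM) 302 and 157 of TPCD, so the class may differ between groups. Squamous-like cells made up 3.52% of cells in TPCD, 0.507% in TY, 0.308% in TP and 0.0774% in TCD, and the groups differed (exact permutation p = 0.022, adjusted 0.038). This call was lost at 2000 UMIs (adjusted p = 0.055), without both libraries named above (0.17) and without any single library of TP, TCD or TPCD (0.056 to 0.11). Immune-like cells made up 22.4% (SD 4.69) in TP, 11.1% (SD 2.53) in TY, 8.39% (SD 0.527) in TCD and 11.5% (SD 4.91) in TPCD (exact permutation p = 0.026, adjusted 0.038). This call was lost at 2000 UMIs (adjusted p = 0.073), without both libraries (0.17) and without TY replicate 1, TPCD replicate 1 or any single library of TP or TCD (0.05 to 0.099). Cycling cells were 5.4 to 21.5% of glandular cells and the test across groups did not pass (exact permutation p = 0.2, adjusted 0.2). Cluster 12 held most of these cells in TY and TP, cluster 17 in TCD and cluster 14 in TPCD, so this class may differ between groups too. Parietal-like cells were 39.3% (SD 2.94) of glandular cells in TY, 14% (SD 4.3) in TP, 11.7% (SD 0.821) in TCD and 0.0618% (SD 0.0874) in TPCD. At most 15% mitochondrial UMIs they were 5.58 and 10.8% in TY, 2.44, 1.42 and 15% in TP replicates 1 to 3 and 2.1, 4.06 and 3.9% in TCD replicates 1 to 3. Pit-like cells were 16.2, 42.2, 19.7 and 0.0911% and chief-like cells 10.8, 8.11, 5.48 and 0% in the same order. Epithelial cells of no named class were 15.9, 18.9, 45.9 and 82.2%. These last shares are values with no test, since different clusters held most of these classes in different groups (for chief-like cells at Leiden resolution 2 only). Unassigned cells were 12.4% of the library labelled TP replicate 3 and 22.1% of the library labelled TCD replicate 1.

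**Figure D3:**
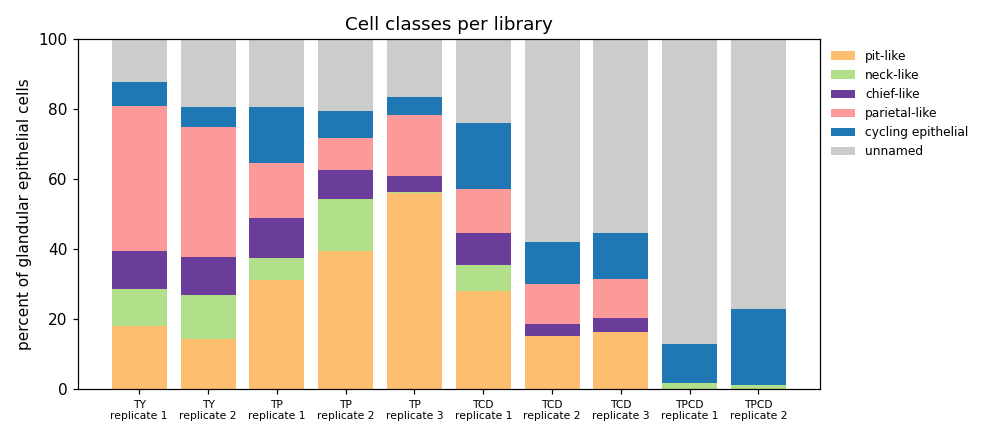
Stacked bars of the percent of glandular epithelial cells in each class (vertical axis) per library (horizontal axis). Parietal-like cells averaged 39.3% in TY and 0.0618% in TPCD, where 82.2% of cells had no named class.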

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

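The tests of a label exchange, of a shared litter background, of free RNA by library, of the filters on barcodes, of losses by cell type and of the pit-like share under another stomach region were chosen after the results were seen. The intervals used for the first pair and the counts of genes shared with TPCD against TY were also added then. For the library labelled TP replicate 3, the same condition had been written before for both causes together, free RNA and low quality.

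The response to loss of Pten differed with Kmt2c and Kmt2d in 1063 epithelial genes, by edgeR's interaction test (adjusted). The largest differences above the sum of the separate changes, in log2 fold, were Cldn7 at 6.63, Cxcl1 at 6.13, Tenm4 at 4.94, Gcnt2 at 4.66, S100a10 at 3.90, Phlda1 at 3.89, Plet1 at 3.29 and Rhof at 3.18. The largest below it were Gif at -8.23, Pga5 at -5.87, Adh7 at -5.55, Serpinh1 at -5.15, Ces1f at -4.96, Ifi27l2a at -4.90, Oit1 at -4.61 and Bpifb1 at -3.52. Gcnt2 shows what the contrast holds: its mean CPM was 62.1 in TY, 9.97 in TP, 10.4 in TCD and 42.2 in TPCD.

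Lists whose interaction passed camera and fry, a rule set after the result was seen, had these median log2 folds. Medians were positive for squamous genes (2.68, or 3.55 with 7 members at their floor), NF-kB genes (1.62, or 1.61 with 3 at the floor), claudins (1.62), glycolysis (1.14), hypoxia (1.02), TGF-beta genes (0.98, or 1.12 with 1 at the floor), cholesterol synthesis (0.92), p53 targets (0.89) and metaplasia genes (0.52). They were negative for red cell markers (-11.18), chief (-5.75), interferon (-3.81), endocrine (-2.01), pit (-1.74), MHC class I (-1.64) and parietal genes (-1.61). No list passed with an estimated correlation.

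EYFP transcripts, which no comparison used, averaged 1700 CPM (SD 53) in TPCD epithelial sums and 1300 CPM (SD 160) in TY. Over all barcodes EYFP had 79367 and 89304 UMIs in TY and 267284 and 272698 in TPCD, but 34, 1 and 0 in TP replicates 1 to 3 and 2, 2 and 0 in TCD replicates 1 to 3. TY and TPCD thus carry the reporter transcript and TP and TCD lack it. The interaction contrast sets exactly these pairs of groups against each other, and TP or TCD against TY and TPCD against TP or TCD set 1 group with it against 1 without, so a difference that goes with the reporter allele or its colony and an effect of the deletions cannot be told apart in TP or TCD against TY. Such a difference alone would leave TY and TPCD alike, so it is not the only difference in genes that also passed, in the same direction, in TPCD against TY. These were 79.5% of the genes called in TPCD against TP, 78.5% in TPCD against TCD and 64.3% in the interaction (684, among them Cldn7, at 7.63 CPM in TY and 312 in TPCD). All come from the same TPCD libraries. Their folds against TP or TCD and in the interaction are other contrasts than TPCD against TY. The part of the reporter in those folds therefore stays open, as it does for the other genes.

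The libraries labelled TP replicate 3 and TCD replicate 1 lay nearer to the other group than to their own. Across genes, which are not independent replicates, epithelial sums of the former correlated at 0.963 with TCD replicates 2 and 3 and at 0.931 with TP replicates 1 and 2, and those of the latter at 0.930 and 0.978, while in immune-like and stromal cells these were 0.836 and 0.829, and 0.857 and 0.860. After free RNA was subtracted the former still correlated better with the TCD side, by 0.0484, as the condition written against free RNA required. That subtraction took an estimated 63.8% of its UMIs, and its correlations with the other libraries were then only 0.435 to 0.617, so this cannot decide. The latter correlated better with the TP side by only 0.00635. Free RNA stays open for both libraries, and so does low quality, which subtraction does not test. Of 6 genes 16-fold apart in epithelial and other cells, 3 (exact 95% interval 11.8 to 88.2%) put the former on the TCD side and 0 the latter in epithelial cells (3 and 1 in other cells), and 6 of 19 genes (31.6%, interval 12.6 to 56.6%) apart in epithelial cells were also apart in other cells. At face value these met the conditions written against an exchange and against a litter background. Immune-like shares (24.1% in the former, 25.9 and 17% in TP replicates 1 and 2, 8.96% in the latter, 8.29 and 7.92% in TCD replicates 2 and 3), mast-like shares and Pten in the former (63.6 CPM) went with the labels. In the former, 1620 of the cells lay in myeloid cluster 15 (21.5% doublets, Cldn18 911 CPM) and 437 in mast cluster 26 (29.9% doublets). Mast cluster 20 (3.5% doublets) held 54 of its cells, against 496 and 395 of TP replicates 1 and 2. Its immune-like and mast-like shares thus weigh little for its label. Neck-like shares (0.108% in the former, 6.12 and 14.9% in TP replicates 1 and 2, 7.4% in the latter, 0.168 and 0.124% in TCD replicates 2 and 3) and chief-like shares lay nearer to the other group. So did Pten in the latter (58.5 CPM), and Kmt2c (47.8 and 170 CPM) and Kmt2d (10.7 and 23.2 CPM) in both. With only the Kmt2c and Kmt2d status of both libraries exchanged and their Pten status kept as labelled, the average Kmt2c and Kmt2d effect held 5221 genes, against 4374. A fit with the labels fully exchanged was not run. The intervals reach past those conditions and each group has only 2 other libraries, so an exchange, a litter background and a difference between mice cannot be told apart.

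Interferon genes stood higher in TP and TCD than in TY. A state of the whole tissue would raise them in other cells too, but the ratio of the list's median log2 fold in immune-like and stromal cells to that in epithelial cells was at most -0.0537 (3.66 in epithelial cells and -0.298 in other cells for TP against TY). These cells were pooled over classes whose shares differed between groups (endothelial-like 6.26% in TY, 1.62% in TP and 0.347% in TCD). The ratio thus shows no matching rise over the pooled cells, but make-up may enter it. Free RNA from immune cells would make the rise shrink on subtraction, but at least 0.907 of it stayed. The profile subtracted rested on only 18621 to 150604 UMIs per TP or TCD library. It was thus coarse for genes of low level, and free RNA is not ruled out for these. In TPCD, which carries the reporter transcript as TY does, the list's median log2 fold against TY was 3.15, so the reporter does not account for that rise. An effect of the deletions may remain as a hypothesis, and in TP and TCD a difference tied to the reporter allele stays open beside it.

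Pit-like, chief-like and parietal-like cells were nearly absent from TPCD. Loss to the filters would leave transcripts over all barcodes. Chief and parietal levels in TPCD (Pgc with Gif, Atp4a with Atp4b) were there at most 0.268% of the lowest other library, which argues against that loss for those cells. Loss in dissociation was predicted to leave transcripts in barcodes with 10 to 100 UMIs, where these levels were at most 0.488%. Viable cells were sorted after digestion, so RNA of cells broken earlier need not reach these barcodes. Loss in dissociation therefore stays open for chief-like and parietal-like cells. A sum of these genes with Gkn1 and Muc5ac, at most 7.09 and 7.76%, mixes the cell types and decides nothing for pit-like cells, whose Gkn1, Tff1 and Muc5ac stood at 46.2 and 59.2% over all barcodes (Gkn1 at most 27.5% and Muc5ac 6.9%) and at 42.9 and 69.5% in barcodes with 10 to 100 UMIs, between the conditions written for and against, so both losses stay open for these. Sampling of another region could give this pattern: the antral gene Pdx1 stood at 44.6 and 27.9 CPM in TPCD, the lower of them 4.1 times the highest other library, as the prediction for that cause required. Gast, the antral hormone gene, stood at 5.0 and 2.61 CPM in the epithelial sums, which leave out endocrine cells, so it decides nothing on region. At Leiden resolution 2 the endocrine cluster led by Gast (cluster 53) held 25 and 9 cells of TPCD and 10 and 43 of TY. Endocrine cluster 19, led by Chga, held 1 and 1 of TPCD and 234 and 461 of TY. Gkn1, Tff1 and Muc5ac in epithelial sums reached at most 52.2%, which left open how far region accounts for the low pit-like share. Region, loss in dissociation and an effect of the deletions all stay open.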

How the results depend on the processing

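Counts of epithelial genes are given in the order TP, TCD and TPCD against TY, TPCD against TP, TPCD against TCD, average Pten effect, average Kmt2c and Kmt2d effect and interaction, and the cause of each change was not tested unless stated. The counts were 67, 535, 5415, 4757, 3425, 2167, 4374 and 1063. RLE factors and at least 2000 UMIs per cell left them within 1.5 times. With free RNA subtracted they were 8, 18, 1881, 1958, 1025, 314, 1273 and 192. Thinned to 1000 UMIs per cell they were 117, 306, 2802, 2364, 1453, 857, 2310 and 454. At most 15% mitochondrial UMIs gave 13, 12, 3355, 820 (average Pten), 2906 (average Kmt2c and Kmt2d) and 564 (interaction). DESeq2 gave 729 (252 higher, 477 lower), 1907 (815 higher, 1092 lower), 3446 (average Pten) and 2189 (interaction). A fit of only the groups compared, with fewer samples, gave 2, 103, 10201 and 2895 for the first 4. No filter on low counts gave 44 and doublets kept gave 40 for TP against TY. Without both doubted libraries (labelled TP replicate 3 and TCD replicate 1), chosen after seeing the data, they were 3495, 7566, 10876, 10525, 8649, 7397, 10467 and 5201.

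Left out in turn, single libraries gave 2 to 195, 5 to 2200, 2250 to 7948, 1850 to 7063, 1204 to 5869, 637 to 3798, 2065 to 6954 and 234 to 2330. Where this left TY or TPCD with 1 library, that library is assumed to vary like the other groups.

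TP and TCD share replicate numbers 1 to 3, whose deviations correlated at 0.606, -0.51 and 0.618, and TP replicate 3 correlated best, at 0.642, with TCD replicate 2, so the numbers were not taken to pair the samples. Same-number TY and TP pairs correlated at 0.186 and 0.215, and cluster 13 held 651 cells of TY replicate 2 and 1261 of TP replicate 2 but at most 1 of any other library, so these libraries may share a batch that the labels do not give. With the replicate number as a block the counts were 162 and 850 for TP and TCD against TY, and the other epithelial counts stayed within 1.5 times. In classes the block gave 23 and 37 (pit-like, TP and TCD), 41 (neck-like, TP) and 20 and 33 (chief-like, TP and TCD). It moved the correlation of Pten effects to 0.113 and of Kmt2c and Kmt2d effects to 0.316.

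In pit-like cells, against 0 genes, TP against TY gave 70 by DESeq2 (67 higher), 580 without both doubted libraries, and 1 with no filter, at Leiden resolution 2, thinned, or with only the groups compared, and 0 to 3 with single libraries left out. TCD against TY gave 132 (93 higher), 2865, 2 with only the groups compared, and 0 to 1. In neck-like cells the 12 genes of TP against TY became 63 by DESeq2, 84 with no filter, 5 with free RNA subtracted and 2 to 39 with single libraries left out, and the 4842 of TPCD against TY became 890 thinned and 3433 to 4788. In chief-like cells the 11 genes of TP against TY became 58 by DESeq2 (50 higher), 32 with no filter, 74 without both doubted libraries, 20 with doublets kept, 126 with free RNA subtracted, 1 thinned, 7 with only the groups compared and 1 to 27. The 10 of TCD against TY became 52, 25, 800, 19 at Leiden resolution 2, 0 with free RNA subtracted, 2 thinned, 21 with only the groups compared and 1 to 38.

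The correlation of Pten effects, 0.186, became 0.102 with no filter and 0.0412 with free RNA subtracted (0.0947 to 0.254 with single libraries left out). That of Kmt2c and Kmt2d effects, 0.369, became 0.244, 0.247 and, without both doubted libraries, 0.499 (0.314 to 0.415). Of 280 list tests camera called 144 and fry 108, and 0 passed with an estimated correlation.

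Between the highest and lowest group, squamous-like shares differed by 3.597 points at 2000 UMIs (adjusted exact p = 0.055) and 3.431 without both doubted libraries (0.17), and by 2.447 to 4.427 with single libraries left out (adjusted p 0.0024 to 0.11). Immune-like shares differed by 11.3 (0.073), 13.37 (0.17) and 12.18 to 16.62 (0.02 to 0.099), and cycling shares by 8.382 to 15.29. TPCD minus TY at most 15% mitochondrial UMIs was -17.02 points for neck-like, -17.79 for chief-like and -8.128 for parietal-like cells. With single libraries left out it was -17.94 to -14.28 (pit-like), -11.28 to -9.255 (neck-like), -10.87 to -10.71 (chief-like) and -41.32 to -37.15 (parietal-like).

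Of 128 folds named by size, 52 kept their call and direction under every alternative and 2 changed sign. For Tnfaip3, average Pten effect, 2.40 (SE 0.14) became -3.58 (SE 0.63, edgeR adjusted p = 0.055) with free RNA subtracted, and Rell1 (same effect) became 0.09 at most 15% mitochondrial UMIs. The other sign changes were in the targeted genes. Kmt2c in TP against TY ran from -0.32 to 0.32 with single libraries left out, was 0.04 without TY replicate 2 and 0.32 without TP replicate 3, and became 0.32 without both doubted libraries (edgeR adjusted p = 0.033), 0.15 with the block and 0.14 thinned. Kmt2c in TCD against TY ran from -0.37 to 0.14, with 0.04, 0.13 and 0.14 without TY replicate 2, TCD replicate 2 or TCD replicate 3, 0.31 with the block and 0.12 thinned, and its average Pten effect 0.11 without both doubted libraries. Pten in TPCD against TP became 0.09 at most 15% mitochondrial UMIs. With free RNA subtracted Kmt2d became 0.25 in TPCD against TP, 0.35 against TCD and 1.58 in the interaction, which ran from -0.54 to 0.08 (without TCD replicate 1) with single libraries left out. Per library, free RNA was estimated at 6.8 to 63.8% of UMIs, highest in the library labelled TP replicate 3.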

Other observations

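The tests in myeloid-like and fibroblast-like cells and in T and NK-like cells were chosen after seeing the data, as were the genes named here. In myeloid-like cells of TPCD against TY 106 genes rose and 32 fell (138, edgeR; 360 by DESeq2). Glycolysis, hypoxia and TGF-beta lists passed camera and fry upward (median log2 folds 1.68, 1.93 and 1.43, with 2 of 15, 5 of 14 and 0 of 12 genes higher) and MHC class II genes downward (-2.39), while NF-kB genes (median 1.85, 3 of 19 higher) passed camera (adjusted p = 4.74e-08) but not fry (0.0851). The chemokine gene Cxcl3 reached 1250 CPM (SD 866) against 3.69, a log2 fold of 8.48 (SE 1.49, adjusted p = 0.029). The interleukin gene Il23a reached 248 CPM (SD 11.4) against 1.17 (7.91, SE 1.10, adjusted p = 0.0063). The activin gene Inhba (293 CPM), Hal (166 CPM) and the cytokine gene Lif (29.6 CPM) had no counts in TY. Against TP 279 genes passed (29 to 1007 with single libraries left out, 1743 without both doubted libraries, labelled TP replicate 3 and TCD replicate 1) and against TCD 217 (18 to 1186, and 1618). Left out in turn, single libraries gave 0 to 1165 genes against TY, and 1726 passed without both of these. Cluster 11 held most of these cells in TY and TCD, clusters 11 and 15 in TP, and clusters 29 (led by S100a9) and 30 (led by Tnf) in TPCD, so the changes may be of cell type. Epithelial genes also moved in these sums: Pgc and Atp4b fell, Krt14 rose from 0.382 to 54.3 CPM (6.74, SE 0.95, adjusted p = 0.0077), and squamous genes (median 5.61) passed camera (adjusted p = 0.000318) but not fry (0.157), so RNA of other cells may add to the changes, which was not tested here.

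In fibroblast-like cells of TPCD against TY 15 genes rose and 3 fell (18, edgeR; 190 by DESeq2), and single libraries left out gave 0 to 249. Cluster 27 held most of these cells in TY and cluster 32, which Mmp10 leads, in TPCD, so these too may be changes of cell type. The metalloprotease gene Mmp10 stood at 4280 CPM against 0 and Mmp13 at 1870 against 0.592. Il11 stood at 1110 CPM (SD 565) against 4.57 (8.05, SE 0.81, adjusted p = 0.0095) and the collagen gene Col12a1 at 1100 CPM (SD 190) against 26.4 (5.39, SE 0.50, adjusted p = 0.015). Ereg stood at 1350 CPM and Grem1, which blocks bone morphogenetic proteins, at 832 CPM. The epithelial genes Atp4b (-10.92) and Pgc (-10.66) fell in these sums, and Ereg also rose in the epithelial sums. RNA of other cells may therefore add to these changes, which was not tested here. In T and NK-like cells edgeR called 1 gene in TP against TY (19 by DESeq2, and 14 by edgeR without the doubted libraries). In TCD against TY it called 0 (6 by DESeq2, and 91 by edgeR without the doubted libraries).

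Mast-like cells were 5.24% (SD 1.26) of cells in TP, 2.70% (SD 0.455) in TCD, 0.766% (SD 0.0273) in TY and 0.0788% (SD 0.00764) in TPCD. Endocrine-like cells were 10.4% in TY, 5.03% in TP, 2.87% in TCD and 0.792% in TPCD, and endothelial-like cells 6.26, 1.62, 0.347 and 0.67% in the same order. These shares were not tested.

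For the average Pten effect, of all 100 possible splits 1, the real one, gave as many genes (2167, highest other 1635), which is the fewest possible. The other splits with both TPCD libraries on the side with loss gave 471 to 1635 genes. Splits with all TP libraries on that side but not both TPCD libraries gave 0 to 3. The count thus followed the TPCD pair and does not show a Pten effect shared by both Kmt2c and Kmt2d states. For the average Kmt2c and Kmt2d effect, 2 of 100 gave as many (4374), and the highest other, with 5221, had TY replicates 1 and 2, TP replicates 1 and 2 and the library labelled TCD replicate 1 on 1 side. That split follows the doubted libraries. Other splits with both TPCD libraries on the side with loss gave 334 to 2216 genes. Splits with all TCD libraries on that side but not both TPCD libraries gave 0 to 11. This count, too, thus followed the TPCD pair and by itself does not show an effect shared by both Pten states.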
